A study of Homo sapiens with 4 samples.

How the data were processed

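Total RNA of MKN28 and RMKN28 cells, with 2 samples per line, was labelled with Cy3 from 1 ug of RNA and hybridised to single-colour Agilent whole-genome arrays, per the labels' protocols. The deposited values are spot intensity on a linear scale, not normalised between arrays. Per the file headers they were made with Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes name version 9.5.1. The headers name the array design 014850. The deposited value table holds the same processed intensity as the scanner files (largest difference 0), so its scale is linear, without centring. All arrays came from 1 slide and 1 scan, so no slide block could be fitted. Among non-control spots, 0 were saturated. Saturation of spike-in spots was not counted.

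The processed signal was log2-transformed and reduced by each array's 75th percentile over non-control spots without outlier flags. Spots of a probe were averaged. Of the 41000 probes, 26222 matched 1 gene symbol through their RefSeq accession, 0 matched several and 14778 matched none, using a RefSeq table of assembly GRCh38.p14 for names and gene neighbours only. Its coordinates are not given, since the array annotation uses an older build. A probe was tested if well above background on both arrays of at least 1 line, which left 29588 probes, 20915 of them named. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes) and Benjamini-Hochberg adjustment over all probes tested, with a threshold of 0.05. A gene was read through its tested probe with the highest mean. Several probes were tested for 5014 genes. Among called genes only, 45 had another tested probe called in the opposite direction. Where no probe of a gene was well above background on any array of a line, the fold is a lower bound, from the brighter line's mean against, per array, the higher of the dim signal and the lowest signal among probes well above background. Gene lists were tested with camera at a preset correlation of 0.01, for lists of at least 3 tested genes. Counts of list members cover tested genes only, and listed genes without a tested probe are left out. Camera at an estimated correlation and fry were also run. The form with an estimated correlation takes its degrees of freedom from the 4 arrays alone, so it can hardly call any list.

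Before the data were examined, 29 gene lists, most of the alternatives and the rule for named genes were fixed. Normexp on the median spot signal, spike-in scaling, the crossed replicate block and subtraction of the neighbouring genes' median were added later. The rule for named genes takes the 10 largest rises and 10 largest falls among called genes well above background on all arrays, and the 5 largest bounds in each direction. It also takes any tested member of the gemcitabine and dNTP lists, and up to 4 called members of each other list. Genes of lists added later were chosen after their values were seen.

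The fit was tested on simulated arrays with the means of the 29588 probes. Noise was drawn independently for each probe from the distribution of variances that limma fitted. Of 50 probes changed at each log2 size, limma called 0 at 0.5, 18 at 1, 46 at 2 and 49 at 3. A stricter requirement, that all 50 be called at each of the 2 largest sizes, was set at first and not met. These recovery rates hold where few probes change, and are not the power in the data, where 12152 probes were called. Of 29388 unchanged probes 8 were called. With 11835 changed probes, limma made 6782 calls, of which 3.16% were false. Camera called the 1 shifted list and 0 of 20 unshifted lists. Since probes were simulated independently, this does not test the effect of correlation between genes.

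Alternatives were quantile normalisation, array medians, other filters on dim probes, replicate blocks, leaving out each array, the deposited value table, a trended robust prior, the mean of a gene's probes, other thresholds, normexp background correction, spike-in scaling and subtraction of the median of the 10 genes on each side. The files hold no mean spot signal, so normexp used the median spot signal. Figures were drawn with matplotlib 3.10.9.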

Results

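Gene expression was measured in MKN28, a human gastric cancer cell line, and in RMKN28, a derivative made resistant to gemcitabine by exposure at the half-inhibitory concentration and then stepwise 10-fold increases to 10000 ng per ml. Gemcitabine is a deoxycytidine analogue that cells take up, phosphorylate and build into DNA. The submitters' design asks which transcripts differ between the resistant and the parental line. Each line had 2 arrays, and all 4 arrays lay on 1 slide, MKN28 at positions 1 and 2 and RMKN28 at positions 3 and 4, so that position and cell line cannot be told apart. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. On the MKN28 arrays 30992 and 27896 of the 41000 probes were well above background, and on the RMKN28 arrays 29977 and 29986. The 75th percentile of the signal was 2123 and 2052 for MKN28 and 2346 and 1739 for RMKN28. The number of arrays limits the precision of every value.

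Several of the largest rises in RMKN28 were in genes of basal epithelial attachment and keratins, although the list of epithelial junction and keratin genes showed no common direction. COL17A1, a collagen of hemidesmosomes, was 53.4-fold higher (log2 difference 5.74 ± 0.24, SE, limma adjusted p = 0.00036), LAMA3, the alpha chain of laminin-332, 32.2-fold higher (5.01 ± 0.12) and KRT6A, a keratin of stressed or stratified epithelium, 29.8-fold higher (4.90 ± 0.09). KRT6C was 34.7-fold higher, but its probe is uncertain because KRT6A and KRT6C are near-identical. Other large rises were those of INHBA, which encodes the activin A subunit (21.2-fold), the adhesion molecule CEACAM6 (20.5-fold), NAV3 (19.7-fold) and CAVIN3, a caveolar coat protein (18.4-fold). SPANXA1 (18.6-fold) and SPANXD (18.2-fold), testis-specific genes of 1 near-identical family, cannot be separated with certainty. Where several probes of these genes were tested, their log2 differences ranged from 4.78 to 5.74 for COL17A1, from 3.54 to 5.01 for LAMA3, from 3.07 to 4.20 for CAVIN3 and from 4.30 to 4.94 for NAV3.

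The deepest falls in RMKN28 among genes well above background on all arrays were those of HCLS1 (log2 difference -5.16 ± 0.10, limma adjusted p = 0.000164), SIGLEC6 (-4.91 ± 0.10), the iron exporter SLC40A1 (-4.34 ± 0.09), BAIAP2L2 (-4.16 ± 0.14), TMT1A (-4.08 ± 0.09), SECTM1 (-4.05 ± 0.09), CAPN6 (-3.91 ± 0.22), the protease TMPRSS3 (-3.85 ± 0.10), the siderophore-binding protein LCN2 (-3.81 ± 0.14) and PRDM16 (-3.73 ± 0.19). The tested probes of SECTM1 ranged from -4.05 to -0.81 and those of SIGLEC6 from -4.91 to -3.87.

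Some genes were not well above background on any array of a line, and their folds are lower bounds against the dimmest signals well above background. The desmosomal cadherin DSG3 was at least 57.2-fold higher in RMKN28, SLC7A7, an amino acid transporter subunit, at least 40.3-fold, PKIB at least 18.0-fold, MSN, which links the membrane to actin, at least 14.2-fold and TUSC3 at least 10.9-fold. In the other direction, DSCR8 was at least 27.7-fold higher in MKN28, the histamine-degrading enzyme HNMT at least 27.4-fold, NLRP7 at least 15.4-fold, and PLAAT3 at least 15.2-fold. The neuropeptide gene NTS was likewise above background only in MKN28. All 10 were called by limma. The other tested probes of MSN (3.78) and HNMT (-5.93) gave smaller log2 differences than the probes used (5.47 and -6.76). Among called genes, 102 were well above background in RMKN28 and on no MKN28 array, and 58 the reverse.

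In all, 5897 of the 14308 genes tested (41.2%) differed, 3250 higher and 2647 lower in RMKN28, and 1309 of them differed at least 2-fold, 729 higher and 580 lower. Replicate arrays of a line differed with an SD of 0.27 (MKN28) and 0.24 (RMKN28) on the log2 scale across probes, and arrays of different lines with an SD of 0.68 to 0.69. The direction split depends on scaling. Of the calls, 55.1% were higher in the main setting, 40.0% with array medians and 94.6% with spike-in scaling, which calls 11678 genes. Without RMKN28 replicate 1 the count of called genes was 3839.

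Among genes that take up and activate gemcitabine, 5 of 9 tested were lower in RMKN28 and 1 higher, also when adjusted over the list alone (5 and 1). DCK, the kinase of the rate-limiting phosphorylation, fell by 0.68 ± 0.12 on the log2 scale (1.61-fold, limma adjusted p = 0.0102). The nucleoside transporters SLC29A1 and SLC29A2 differed by -0.45 ± 0.11 and -0.75 ± 0.13, TK2 by -0.37 ± 0.09 and NME4 by -0.73 ± 0.09, while CMPK1, the kinase of the following step, was higher (0.50 ± 0.09). The other tested probes gave -0.45 for DCK, -0.24 for SLC29A2 and -0.22 for TK2. NME1 (-0.13) and NME2 (-0.13), near-identical neighbours, and SLC28A1 (0.12) did not pass the test. Among inactivating genes 4 of 8 were higher and 0 lower, or 4 and 1 adjusted over the list alone. CDA, which deaminates gemcitabine, was 2.96-fold higher (1.57 ± 0.15, limma adjusted p = 0.00208) and the nucleotidase NT5E 4.36-fold higher (2.12 ± 0.09, limma adjusted p = 0.00036). The nucleotidases NT5C2 (0.37 ± 0.09) and NT5C3A (0.52 ± 0.09) were also higher. DCTD (-0.01) and DCTPP1 (-0.29) did not pass the test over all genes, and the other tested probe of DCTD gave 0.40. The tested probes of NT5E ranged from 1.36 to 2.12. Of 15 genes of dNTP synthesis, 2 were higher and 3 lower, with the same counts adjusted over the list alone. RRM1, the large subunit of ribonucleotide reductase, was 1.63-fold higher (0.70 ± 0.11) and TYMS 1.37-fold higher (0.46 ± 0.09), while the small subunits RRM2 (0.07 ± 0.09) and RRM2B (0.17 ± 0.10) did not pass the test. TK1 (-0.63 ± 0.12), CAD (-0.50 ± 0.12) and DHODH (-0.40 ± 0.10) were lower. As lists, these 3 were not called by camera (adjusted p = 0.0828, 0.366 and 0.557), while fry, which does not compare a list with other genes, called the first lower (adjusted p = 0.0255) and the second higher (adjusted p = 0.0150).

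**Figure D1:**
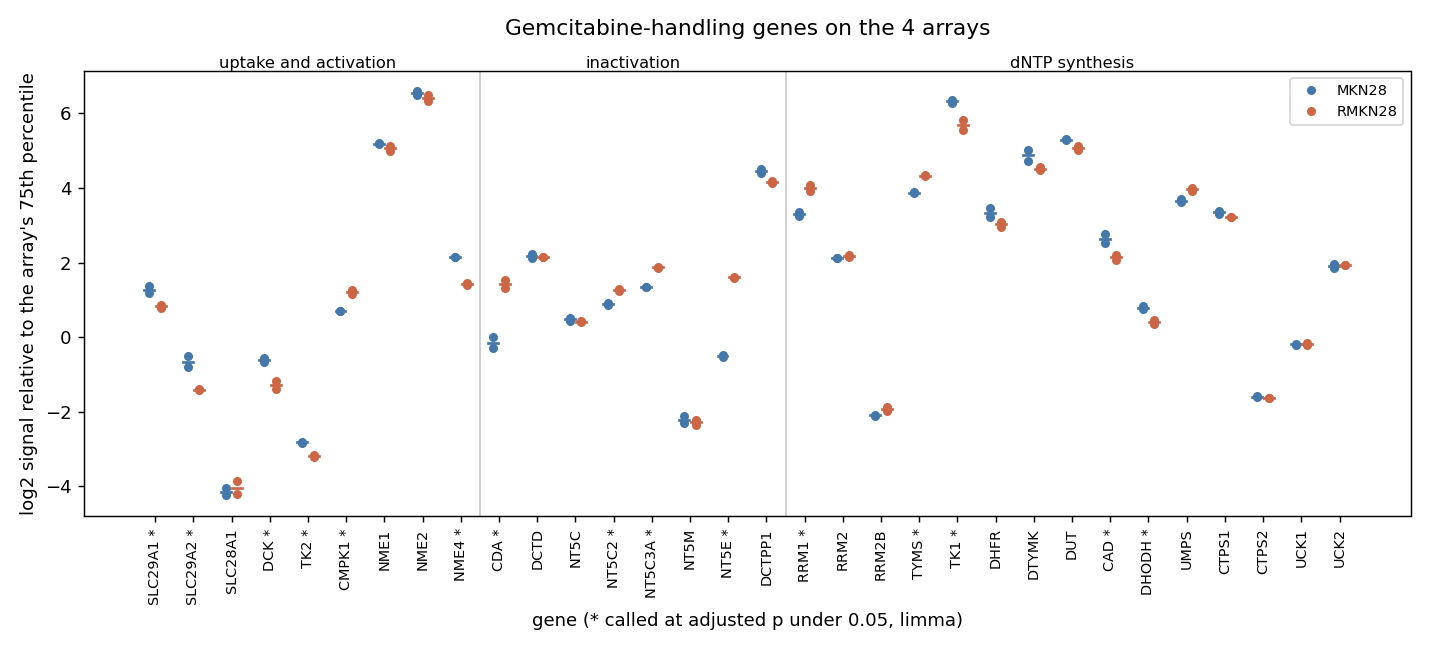
Signal of each tested gene of the gemcitabine and dNTP lists on the 4 arrays, as log2 relative to the array's 75th percentile, with points for arrays and bars for the mean of 2. CDA and NT5E lie higher and DCK lower in RMKN28, while the RRM2 means differ by less than their standard error (0.07 ± 0.09).

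Leaving out 1 array ended the calls of several of these genes with no change of direction. The calls of DHODH (-0.45 to -0.34), NT5C2 (0.35 to 0.40) and TK2 (-0.41 to -0.33) were lost without any of the 4 arrays in turn. Those of SLC29A1 (-0.55 to -0.35), CAD (-0.62 to -0.39), TYMS (0.45 to 0.47) and TK1 (-0.76 to -0.49) were lost in 3 of the 4 fits, and those of CMPK1 (0.45 to 0.55) and NT5C3A (0.51 to 0.53) in 2 of the 4. With spike-in scaling SLC29A1, TK1, TK2, CAD and DHODH turned positive without a call, and DCK (-0.05), NME4 (-0.09) and SLC29A2 (-0.11) stayed negative without one. Without a filter on dim probes the calls of CAD, CMPK1, DHODH, NT5C2, SLC29A1, TK1, TK2 and TYMS were lost, with array medians that of NT5C2 and with normexp without spots dimmer than their background that of TK2. After subtraction of the median of neighbouring genes, the differences of RRM1 (0.30), NT5C3A (0.25) and CAD (-0.19) were left without a call. TYMS turned to -0.31 and passed the test. That median was subtracted as a fixed value, so its own error is not counted and the reversal of TYMS stays uncertain.

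Directions of lists are relative to the bulk of the transcripts. With spike-in scaling, which takes the median spike-in deviation of each array over the levels and so moves all differences by 0.64, the median of all genes was 0.70 instead of 0.07, and the medians of the lower lists turned positive for mitosis (0.24), ATF4 (0.35), receptor kinases (0.23), gemcitabine uptake (0.27) and interferon-stimulated genes (0.44), but not for cholesterol (-0.20). The other lists with a median under 0 also turned positive. In that setting 10 mitosis genes were called higher and 3 lower, and 12 ATF4 genes higher and 2 lower. For cholesterol, 2 genes were higher and 8 lower. Genes of cholesterol synthesis and uptake were lower in RMKN28 as a group. Of 21 tested, 19 fell and 0 rose, also adjusted over the list alone, with a median log2 difference of -0.83 (camera adjusted p = 1.27e-08, adjusted p = 0.663 with an estimated correlation). INSIG1, the sterol sensor partner, fell by 2.37 ± 0.09, LSS by 2.04 ± 0.09, DHCR7 by 1.83 ± 0.12 and FDFT1 by 1.59 ± 0.09. The tested probes of LSS ranged from -2.04 to -1.45. Genes of mitosis and G2/M were lower, with 15 of 24 down and 1 up (16 and 1 adjusted over the list alone), a median of -0.40 and camera adjusted p = 4.61e-05 (adjusted p = 0.663 with an estimated correlation). CCNB2 fell by 1.12 ± 0.09, CENPE by 1.04 ± 0.11, CENPF by 0.95 ± 0.15 and PTTG1 by 0.94 ± 0.11. After subtraction of the median of neighbouring genes CENPE was at -0.31 without a call, and with spike-in scaling CENPF was at -0.32 without a call. Of the 33 DNA replication factors, 4 were higher and 4 lower (2 and 3 adjusted over the list alone), with a median of 0.11.

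Metallothioneins were higher, with 7 of 8 called (8 adjusted over the list alone), a median of 2.10 and camera adjusted p = 4.61e-05 (adjusted p = 0.663 with an estimated correlation). MT1E (2.34 ± 0.12), MT1H (2.33 ± 0.11), MT1X (2.33 ± 0.11) and MT1G (2.26 ± 0.12) are near-identical and their probes are uncertain. Of 20 NF-kB and inflammatory genes, 11 rose and 3 fell, with the same counts adjusted over the list alone and a median of 0.54 (camera adjusted p = 0.0329, adjusted p = 0.663 with an estimated correlation). IL6 (11.6-fold, above background on 1 MKN28 array), CSF2 (11.4-fold) and TNF (8.86-fold, with a log2 difference of 3.15, and 1.21 by its other tested probe) rose, while LCN2 fell. Of 11 tested mesenchymal genes (19 listed), 7 rose and 2 fell, with the same counts adjusted over the list alone. Their median was 0.46 (camera adjusted p = 0.0454, adjusted p = 0.663 with an estimated correlation). VIM was higher by both of its tested probes, at least 7.56-fold by the brighter and by a log2 difference of 2.42 by the other, and its difference was 2.44 without RMKN28 replicate 1 and 2.39 without RMKN28 replicate 2, where the other probe has the higher mean. TGFBI was 8.73-fold and MMP9 6.81-fold higher. Of 14 tested intestinal markers (22 listed), 6 rose and 0 fell, also adjusted over the list alone. The list's median was 0.57, or 0.43 with bounds (camera adjusted p = 0.0135, adjusted p = 0.758 with an estimated correlation). The higher markers include CEACAM6, CDX2 (3.25-fold) and VIL1 (at least 1.59-fold).

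Of 23 ATF4 and unfolded protein response genes, 10 fell and 3 rose, with the same counts adjusted over the list alone (median -0.29, camera adjusted p = 0.0426, adjusted p = 0.663 with an estimated correlation). ASNS (-1.45 ± 0.10) and TRIB3 (-1.41 ± 0.12), both ATF4 targets, fell, and ATF3 rose (0.92 ± 0.09). Of 15 tested receptor kinases and ligands (23 listed), 7 fell and 3 rose, or 8 and 3 adjusted over the list alone. Their median was -0.40, or -0.19 with bounds (camera adjusted p = 0.0454, adjusted p = 0.663 with an estimated correlation). The receptor INSR was at least 1.14-fold lower, ERBB2 was lower by 1 of its 2 tested probes (-1.67 ± 0.10) with -0.09 by the other, and the EGF receptor ligands HBEGF (1.44 ± 0.09, and 0.81 by its other tested probe) and AREG (1.42 ± 0.16) rose. With an estimated correlation no list was called. Against the preset 0.01, the estimates were 0.016 for the cholesterol list, 0.028 for the receptor list and -0.046 for the NF-kB list. They were higher for the ATF4 (0.099), mitosis (0.10), mesenchymal (0.15), intestinal (0.64) and metallothionein (0.78) lists. As this form rests on so few arrays, its result does not decide whether correlation between genes explains the calls. Without either MKN28 array the mesenchymal, intestinal, receptor and ATF4 lists lost their calls, leaving 4 lists without MKN28 replicate 1 and 3 without MKN28 replicate 2, where the NF-kB list was lost too. Without RMKN28 replicate 1 the ATF4 list was lost and 7 remained. Quantile normalisation ended the calls of the mesenchymal, intestinal, ATF4 and receptor lists, leaving out the filter on dim probes those of the mesenchymal, intestinal and receptor lists, and the strict filter those of the mesenchymal, ATF4 and receptor lists. Array medians ended the ATF4 and receptor calls, a trended robust prior and both forms of normexp the receptor call, and the neighbour correction the mesenchymal and receptor calls. Spike-in scaling ended the mesenchymal, intestinal, NF-kB and ATF4 calls. A crossed replicate block, which joins samples of unlike number, kept the 4 lower lists and 3 of the 4 higher ones.

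**Figure D2:**
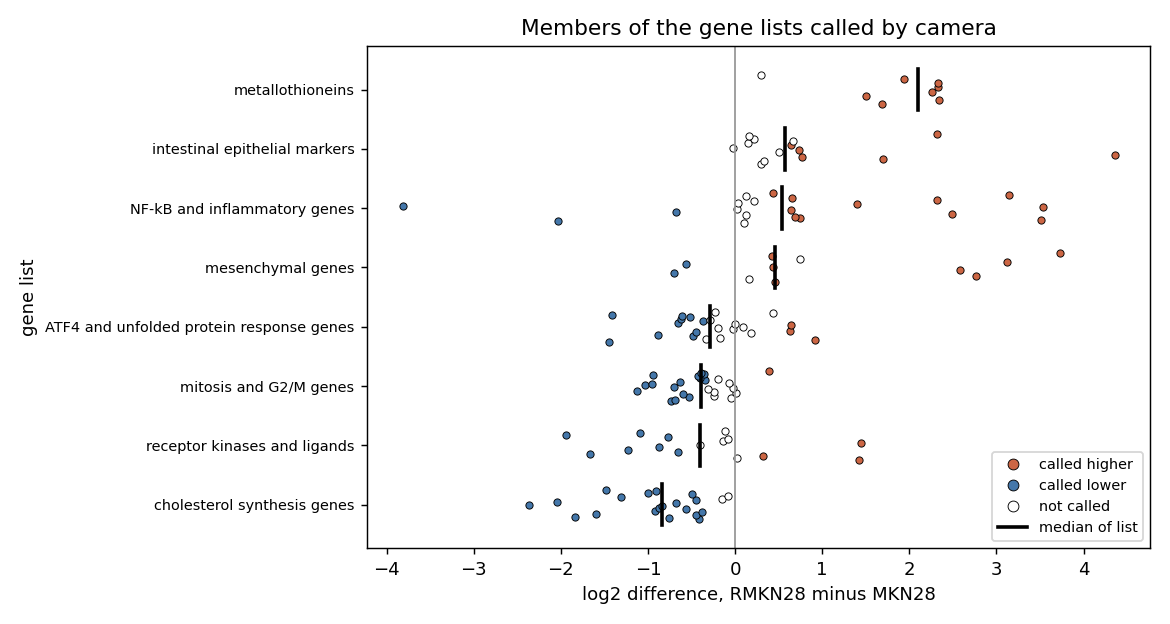
Log2 difference, RMKN28 minus MKN28, of each tested member of the 8 gene lists called by camera, coloured by the limma call, with a bar at the list's median. The cholesterol members lie at or below -0.08 and the metallothioneins above 0, while the other lists hold genes of both directions or near 0.

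The other lists were not called by camera (adjusted p from 0.0828 to 0.992), though members changed. Of those below, fry called the p53, apoptosis inhibitor, stem cell, Wnt and NRF2 lists higher and the interferon list lower. Of 10 ABC efflux transporters 2 rose and 2 fell, ABCC2 by 1.20 ± 0.11 and ABCC3 by 1.16 ± 0.13 upward. The list's median (-0.20) and test point down and its mean (0.04) up. Of 23 p53 target genes 8 rose and 5 fell (9 and 5 adjusted over the list alone), with FAS (2.74-fold) and CDKN1A (2.50-fold) higher and GDF15 lower (-1.08 ± 0.09). Of 40 checkpoint and repair genes 8 rose and 9 fell, with WEE1 higher (1.00 ± 0.09, or 0.37 after subtraction of the median of neighbouring genes) and CHEK1 lower (-0.93 ± 0.16). The CHEK1 call was lost without a filter on dim probes and with spike-in scaling (-0.29). Of 9 apoptosis inhibitors 4 rose, among them XIAP (0.78 ± 0.09), and 1 fell, and of 19 effectors 2 rose and 5 fell, with PMAIP1 4.04-fold higher and BAD lower (-1.16 ± 0.10, or -0.42 after subtraction of the median of neighbouring genes). Of 24 interferon-stimulated genes 12 fell and 3 rose (12 and 5 adjusted over the list alone), HERC5 by -2.69 ± 0.12. With spike-in scaling 12 of them rose and 4 fell (median 0.44), and camera called the list only as lower than the other genes. Of 21 NRF2 and glutathione genes 10 rose and 4 fell (11 and 4 adjusted over the list alone), with GPX2 13.8-fold higher and GSTM3 lower (-2.72 ± 0.09). Counts for the lists of this paragraph with no second count were the same adjusted over the list alone.

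Of 9 stem cell related genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), NES by 1.68 ± 0.10 upward and POU5F1, whose probe can share signal with pseudogenes, by -3.27 ± 0.14 (from -3.27 to -1.65 over its 4 tested probes). Of 12 Wnt targets 7 rose and 1 fell (8 and 1 adjusted over the list alone), NOTUM among the former (1.29 ± 0.11, or 2.19 after subtraction of the median of neighbouring genes). Of 21 epithelial junction and keratin genes 4 rose and 4 fell, with CLDN3 lower (-2.04 ± 0.12, and -0.79 by its other tested probe). The list's median (0.06) lies above 0 and its mean (-0.04) and test below. Of 12 antigen presentation genes 1 rose and 2 fell (0 and 2 adjusted over the list alone), HLA-DMA by -1.71 ± 0.12. Of 21 hypoxia genes 3 rose and 0 fell, SLC2A3 by 1.14 ± 0.10. Of 12 cancer-testis antigens 6 rose and 4 fell, with MAGEC1 higher (1.26 ± 0.09) and MAGEA4 lower (-1.51 ± 0.10). Of 11 gastric markers 0 rose and 1 fell, FUT2 by -1.24 ± 0.09. Markers of other cell types showed no common direction. Of 3 fibroblast markers 0 passed the test, of 8 leukocyte markers 1 rose and 1 fell, and of 4 endothelial markers 1 rose and 2 fell, with a median of -0.09 and a mean of 0.15. Counts for the lists of this paragraph with no second count were the same adjusted over the list alone.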

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

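The test of the spike-in amount was chosen only after the result was seen. Spike-in probes, which report RNA added to each sample and enter no comparison of the lines, were lower on the RMKN28 arrays by a mean log2 difference of -0.56 over 7 levels, relative to the 75th percentile of cellular probes. Averaged over the levels, the replicate arrays of a line differed by at most 0.11, but at a single level by up to 0.20 (MKN28) and 0.24 (RMKN28). The difference ranged from -0.80 to -0.09 over the levels, a range of 0.71, which is what a brightness-dependent bias needs. The 2 brightest levels gave -0.34 and -0.09 and the other 5 from -0.80 to -0.53. Whether spike-in spots were saturated was not checked. The shift itself could also come from more cellular target per added spike-in RNA or from less spike-in RNA added, which cannot be told apart because the amounts added are not given in the sources used here (mean -0.56). With spike-in scaling 11042 genes were higher and 636 lower, so all directions in the text are relative to the bulk of the transcripts.

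Signal also appeared in probes outside the named genes. In RMKN28, 120 called probes without a gene name were well above background that were not so on any MKN28 array, and 69 showed the reverse.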

How the results depend on the processing

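Normexp, spike-in scaling, the crossed block and the neighbour correction were chosen after seeing the data, and normexp on the mean spot signal was not run because the files lack that column. The 5897 genes called became 3084 without a filter (2936 shared), 2805 at an adjusted p under 0.01, 11678 with spike-in scaling, and 3839 to 4618 without 1 array. The 1309 genes called with at least 2-fold became 424 when tested against a log2 difference of 1, 3877 with spike-in scaling and 1379 to 1514 without 1 array. The 8 lists became 4 with quantile normalisation, 5 without a filter, 5 with the strict filter, 5 with spike-in scaling (4 shared, and the interferon list gained), 0 with an estimated correlation, 16 with fry and 3 to 8 without 1 array. Where none is given, the cause was not tested.

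Normexp with all spots gave 0 genes called by limma, and 0 with at least 2-fold, although 2643 had an unadjusted p under 0.05. This is a failure of its fit. On RMKN28 replicate 1, 3 spots lay below their local background, the lowest by -19944, and moved the fitted background mean to -487, against 44.9 to 47.2 on the other arrays. Without these 3 spots it was 53.8, and normexp called 6647 genes (5619 shared), 856 of them at least 2-fold, and 7 lists. The broken fit gave TK2 0.26, and INSR 0.76, and moved the median of all probes to 0.33 from 0.09.

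Spike-in scaling turned SLC29A1 to 0.19, TK1 to 0.012, TK2 to 0.27, CAD to 0.14 and DHODH to 0.24. Subtracting the neighbours' median turned TYMS to -0.31.

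The replicate block called 4546 genes, 1333 with at least 2-fold and 8 lists. Of the genes named in the text, 4 lost their call with this block. Deviations of same-numbered samples correlated at -0.25, which shows no deviation shared by samples of the same number. This correlation alone cannot exclude pairing, since effects of single arrays also enter it. The titles number the samples within each line, without saying whether equal numbers were paired. The crossed replicate block called 7248 genes, 1326 with at least 2-fold and 7 lists. The lone sample of a line in fits without 1 array is assumed to vary like the other line. Signal over background limits dim genes, for which only bounds are given.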

Other observations

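The lists of this paragraph and the tests of parental-type cells and of cycling cells were chosen only after the results were seen. As the genes of these lists were chosen with their values known, the p-values of the lists are not independent evidence of a change. Of 23 squamous and basal epithelial genes 16 were higher in RMKN28 and 2 lower, with a median log2 difference of 1.27 (camera adjusted p = 7.57e-06, adjusted p = 0.318 with an estimated correlation). They include KRT14 (2.95 ± 0.14, and 0.83 by its other tested probe), KRT17 (3.18 ± 0.11) and SPRR1B (3.29 ± 0.12). IVL was lower (-0.67 ± 0.10, or -0.04 without a call with spike-in scaling). After subtraction of the median of neighbouring genes IVL was at -1.23. SPRR1B has the same local median (0.56), so this subtraction is not independent of the higher genes of the list. All 10 genes of hemidesmosomes and laminin-332 were higher (median 1.39, camera adjusted p = 7.57e-06, adjusted p = 0.268 with an estimated correlation), among them COL7A1 (3.47 ± 0.10) and LAMB3 (1.96 ± 0.12). Of 18 TGF-beta and SMAD targets 12 were higher and 2 lower (median 0.94, camera adjusted p = 0.000314, adjusted p = 0.268 with an estimated correlation), with PMEPA1 at 3.67 ± 0.12. Of 9 AP-1 factors 7 were higher and 0 lower (camera adjusted p = 0.0090, adjusted p = 0.318 with an estimated correlation). Of 11 fatty acid synthesis genes 7 were lower and 1 higher (median -0.51, camera adjusted p = 0.00265, adjusted p = 0.268 with an estimated correlation). FASN was at -1.55 ± 0.23, or -0.58 without a call after subtraction of the median of neighbouring genes. Of the 11 genes, 4 lie in runs of lower neighbouring genes. Camera did not call the YAP and TEAD (7 of 13 higher, 4 lower), histone (3 of 11 higher, 5 lower), ribosomal protein (0 of 24 higher, 2 lower) and oxidative phosphorylation lists (3 of 23 higher, 7 lower).

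Neighbouring genes changed together. Across 14293 genes, a gene's log2 difference correlated with the mean of the genes 3 to 7 places away on its chromosome at 0.22, above the highest of 1000 shuffles of gene order within chromosomes (0.09, permutation p = 0.001, the smallest they can give), and at 0.23 among genes that changed by under 1. Genes are not independent replicates. There were 17 runs of at least 31 genes with a running median at least 0.3 from that of all genes, 5 higher and 12 lower, against at most 7 in 200 shuffles. They include 206 genes of chromosome 11 from H19 to CSTPP1 (0.43 higher), 163 genes of chromosome 11 from LINC00301 to PACS1 (-0.55) and 122 of chromosome 4 from CXCL5 to ZGRF1 (-0.72). Cross-hybridisation between paralogs is argued against, since 0.91 of the correlation remained without neighbours of the same family name. Copy number change of segments is a hypothesis that these values meet, but copy number was not measured, and regional regulation of expression stays open. RRM1 lies in the higher run of chromosome 11, where the local median is 0.40, and TYMS beside genes with a local median of 0.76, whereas DCK lies among genes with a local median of 0.16 and CDA of 0.11.

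The squamous keratins could come from squamous cells mixed into the RMKN28 culture. The median of the 6 tested genes of 8 listed was 1.17, above the bound of 1 set in advance, but only 3 of the 6 exceeded it and KRT15 (0.23 ± 0.13) did not pass the test. The other listed genes, TP63 and DSC3, were well above background on 0 arrays, and with both at 0 the median would be 0.91, under the bound, so the test does not decide. Unchanged parental-type cells as the main part beside a second population are argued against, because 12 genes above background on all arrays fell more than 10-fold. Altered expression in the selected cells and replacement by another population stay open, since no reference profile was used here.

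A smaller share of cycling cells, as the source of the lower mitotic genes, needed the DNA replication factors to fall as well (median under -0.2). A median that was not negative was to argue against it. Their median was 0.11 in the main setting, so these genes did not fall with the mitotic genes. With array medians it was -0.0047, between the bounds. As the bounds were set after the results were seen and directions depend on the scaling, the test does not decide.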
